A study of Mus musculus with 3 samples.

How the data were processed

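Nuclear RNA was measured in the hippocampus of 3 wild-type mice that were 1 year old, all in group Control (replicates 1 to 3). Per the labels, nuclei were released from homogenised tissue with detergent, stained with the DNA dye DRAQ7 and sorted by particle size and dye signal. In each library 75000 nuclei were sorted and 12000 were loaded on a droplet controller, which gives the RNA of each droplet a shared barcode and each molecule a UMI. Sorting by size favours or removes nuclei by their dimensions, so shares of classes describe the nuclei sorted, not the tissue. Per the labels, the libraries were made with a kit that reads the 5′ end of transcripts, and which end was read was not tested here.

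The deposited matrix of replicate 3 holds raw UMI counts per gene and barcode, with no normalization. Per the submitters' processing notes, reads were processed with Cell Ranger 6.0.2 against mm10, and the matrix is of the filtered kind, which holds the barcodes called as nuclei. The deposited lists of replicates 1 and 2 hold barcode names and gene names, which carry no measurement and were used as other information, for the number of barcodes. Whether intronic reads were counted, which gene annotation was used and whether filters beyond cell calling were applied is not given in the sources used here. Count matrices of replicates 1 and 2 were not used here. Gene IDs were matched to the GENCODE vM21 annotation of GRCm38, the assembly also named mm10, in which 31011 of the 31053 listed gene IDs (99.9%) were found. Genes were named by symbol, and 36 symbols that stand on several IDs were kept apart.

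Malat1, a nuclear noncoding RNA, took 20.6% of the UMIs of replicate 3. The mitochondrial share of UMIs was at most 4.95% of a barcode, with a median of 0.0274%. Barcodes with fewer than 500 genes (944) were left out, and the maximum of 5% mitochondrial UMIs removed 0. Doublets, droplets with more than a single nucleus, were scored on the 12482 remaining barcodes by a separate implementation of the Scrublet method, with 2 simulated doublets per nucleus and exact nearest neighbours. The threshold of 0.209, the minimum between the modes of the simulated scores, called 483 barcodes, which were left out. Counts were scaled to 10000 per nucleus and log transformed, 3000 variable genes among those found in at least 10 nuclei were chosen, and 30 principal components were computed. Nuclei were joined in a graph of 15 shared nearest neighbours and clustered with the Leiden method at resolution 1 and seed 1. The 282 genes of the fixed lists were left out of the clustering, so that they could be compared between classes.

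Each of the 25 clusters was named after the cell type whose marker genes, fixed before the data were examined, had the highest mean log2 fold over all other nuclei, with 5 CPM added to each level. A name required a mean of at least 0.9, at least 3 markers raised 2-fold or more and found in at least 5% of nuclei, and a marker among the 10, or 2 markers among the 25, leading genes found in at least 10% of nuclei. A cluster far shallower than the library needed a marker among the 10. The mean and the rule on leading genes were set after the data were seen. Clusters below them, 2 in all, stayed unnamed and were used in no comparison of classes. A name ending in "-like" states resemblance to a marker list, and no other evidence of identity was used.

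For each comparison of classes, raw UMIs were summed over the nuclei of a class and expressed as CPM of all UMIs of the class. Ratios of CPM carry exact 95% conditional intervals, levels exact 95% Poisson intervals and shares of nuclei exact 95% binomial (Clopper-Pearson) intervals. For a share of 0, the limit given is 3 nuclei of the total, which is lower than the upper end of the exact interval. All of them cover counting error only, and nuclei of a single library are not replicates, so no test between animals could be made. A gene was measured when it had at least 50 UMIs over both classes, and was counted as at least 2-fold higher or lower when its ratio was at least 2 either way and its interval left out 1. Where a class had 0 UMIs, the ratio was computed against 3 counts and written as a limit. The same was done where subtracting background RNA left fewer than 3 counts. For a class at 0 UMIs, the exact interval reaches closer to 1 than this limit. A limit was counted as moved by more than 1.5 times only where the reported ratio lay that far outside it, a rule set after the data were seen. The dentate granule-like class was compared with CA1 pyramidal-like nuclei because no CA3 pyramidal-like cluster was named, and the excitatory-like group held dentate granule-, CA1 and CA2 pyramidal-like nuclei, without mossy cells for the same reason. For the lineage, a neuroblast candidate had UMIs of at least 3 of 9 neuroblast genes and a cycling candidate of at least 3 of 11 cell cycle genes, and the number expected was the sum over nuclei of a class with genes taken as independent. Nuclei were also thinned to 1000 UMIs, which leaves out those below that depth, to compare shares of nuclei at equal depth. Gene families were compared in classes of at least 50 nuclei.

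The 12 highest and the 12 lowest ratios of each comparison, among measured genes of 12 fixed lists that passed the rule of size, were named, with Ptbp1, Ptbp2, Dcx, Sox2, Mki67, Notch1, Notch2 and Gfap whatever their value. Of these ratios, 3 are not reported here. Alternatives fixed before the data were examined changed the gene minimum to 200 or 1000, the mitochondrial maximum to 1%, the doublet filter, the resolution to 0.5 or 2, the components to 15, the genes clustered, the barcodes to the 12000 deepest, the ratio threshold to 1.5 or 4, the summary to a mean over nuclei and the number of lineage genes to 2 or 4. A further alternative subtracted from each class a share of the library profile, estimated from the markers of other classes. The first estimate used too few marker sets and gave larger shares, and after its values were seen it was widened to the marker sets of all classes outside the branch of a class, of which the lowest was taken. The shares taken were 12.4% in dentate granule-like, 11.2% in microglia-like, 5.36% in oligodendrocyte-like, 5.09% in astrocyte-like and 2.41% in CA1 pyramidal-like nuclei. Each is the largest share that the marker sets allowed, an upper limit, so subtracting it can remove more than the background. Alternatives chosen after seeing the data left Malat1 out of totals, scaled ratios to the median gene, added CA2 to CA1 pyramidal-like nuclei, left out GABAergic-like cluster 13 or astrocyte-like sub-clusters 4 and 6, and defined candidates by 2 or more UMIs of Igfbpl1. Nuclei with Igfbpl1 were at first set beside random nuclei of matched depth, and after those values were seen beside the 20 nuclei of the same class nearest in depth to each, with nuclei drawn several times counted once.

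The rule of size was tested on simulated data made from the summed counts of each comparison, with 100 genes raised or lowered at each of 2 sizes. It called 94% of genes simulated at 4-fold and 96% at 3-fold in astrocyte-like against dentate granule-like nuclei, and 99% and 98% in dentate granule-like against CA1 pyramidal-like nuclei. In GABAergic-like against excitatory-like nuclei it called 96% and 91%, and in microglia-like against astrocyte-like nuclei 96% and 92%. Of unchanged simulated genes, 0.364%, 0.0872%, 0.516% and 0.400% were called, in the same order of comparisons. Both classes were drawn from a shared profile with counting error only. These shares therefore leave out variation between nuclei or animals, background RNA, doublets and misassigned nuclei, and are not error rates of the calls reported. Of 300 doublets planted among 6000 nuclei, each made from nuclei of different classes among the 5 largest, 84.3% were called, with 0.383% of the others. The 6000 nuclei had already passed the doublet filter at the same threshold, so the 0.383% does not measure false calls. This check left the listed genes out of the scoring, which the main scoring did not. In the main scoring 60.0% of all simulated doublets, which include pairs of the same class, lay above the threshold. In 20 simulations of independent lineage genes, 42 to 74 nuclei met the neuroblast definition, with a mean of 55.6.

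The analysis used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, scanpy 1.11.5, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.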

Results

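Nuclear RNA was profiled in droplets from the hippocampus of 3 wild-type mice that were 1 year old, in a series whose title concerns the waking of resting neurogenic niches in the ageing brain. The hippocampus holds the dentate gyrus, where neural stem cells, most of them resting outside the cell cycle, give rise to granule neurons in adult rodents. All 3 libraries belonged to a single Control group, so the comparisons were made between classes of nuclei within a library. Counts of unique molecular identifiers (UMIs), tags that mark single captured RNA molecules, were taken from replicate 3, while replicates 1 and 2 contributed their barcode lists. Replicate 3 held 13426 barcodes, with 500 to 49172 UMIs per barcode and a median of 2813. After filters, 11999 nuclei with a median of 3010 UMIs and 1442 genes were kept. With 1 library there was no replicate check and no test, and every interval below is an exact 95% interval that covers counting error only. In each comparison of classes, genes were named from the 12 highest and the 12 lowest ratios and a fixed set, by a rule set before the data were examined. Any other gene named in such a comparison was chosen after its values were seen.

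The composition of the library addressed which cell types of the neurogenic niche and its surroundings were recovered. Oligodendrocyte-like nuclei, the myelinating glia, formed the largest class, with 4113 nuclei or 34.3% (33.4 to 35.1). CA1 pyramidal-like nuclei, excitatory neurons of the main hippocampal output field, made up 17.8% (17.1 to 18.5), and dentate granule-like nuclei 14.3% (13.7 to 14.9). Astrocyte-like nuclei made up 6.40% (5.97 to 6.85) and microglia-like nuclei, the resident immune cells, 5.69% (5.28 to 6.12). GABAergic-like nuclei, the inhibitory neurons, and oligodendrocyte precursor-like nuclei each made up 3.46% (3.14 to 3.80). Smaller classes were CA2 pyramidal-like, with 135 nuclei, and Cajal-Retzius-like, early-born neurons that secrete reelin, with 49. The vascular and border classes were pericyte or smooth muscle-like with 51 nuclei, endothelial-like with 46, vascular leptomeningeal-like with 38, border macrophage-like with 33 and choroid plexus-like with 15. Neocortical excitatory-like nuclei (652) and thalamic or habenular-like nuclei (115), classes named after regions outside the hippocampus, together made up 6.39% (5.96 to 6.84). Of the former, cluster 12 with 315 nuclei scored a mean log2 fold of 1.026, near the minimum of 0.9. A further 106 nuclei were subiculum or entorhinal-like. No cluster was named after CA3 pyramidal, mossy, ependymal, neural stem, cycling or neuroblast cells. In the CA2 pyramidal-like cluster the CA3 list scored second, with a mean log2 fold of 1.028 against 2.005 for CA2. The CA3 marker Cpne4 was among its leading genes, so this cluster may also hold CA3 pyramidal nuclei. An unnamed cluster of 500 nuclei, 4.17% (3.82 to 4.54), was led by Foxp2, Ctgf and Syt6. It was counted under no region, so the share from outside the hippocampus may differ from 6.39%. The median depth was 1493 UMIs in oligodendrocyte-like nuclei, 1099 in microglia-like and 8503 in CA1 pyramidal-like, and shares depended on the gene minimum. With 1000 or more genes required in place of 500, the oligodendrocyte-like share was 15.3% and the microglia-like share 2.45%, while the CA1 pyramidal-like share was 25.8%.

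**Figure D1:**
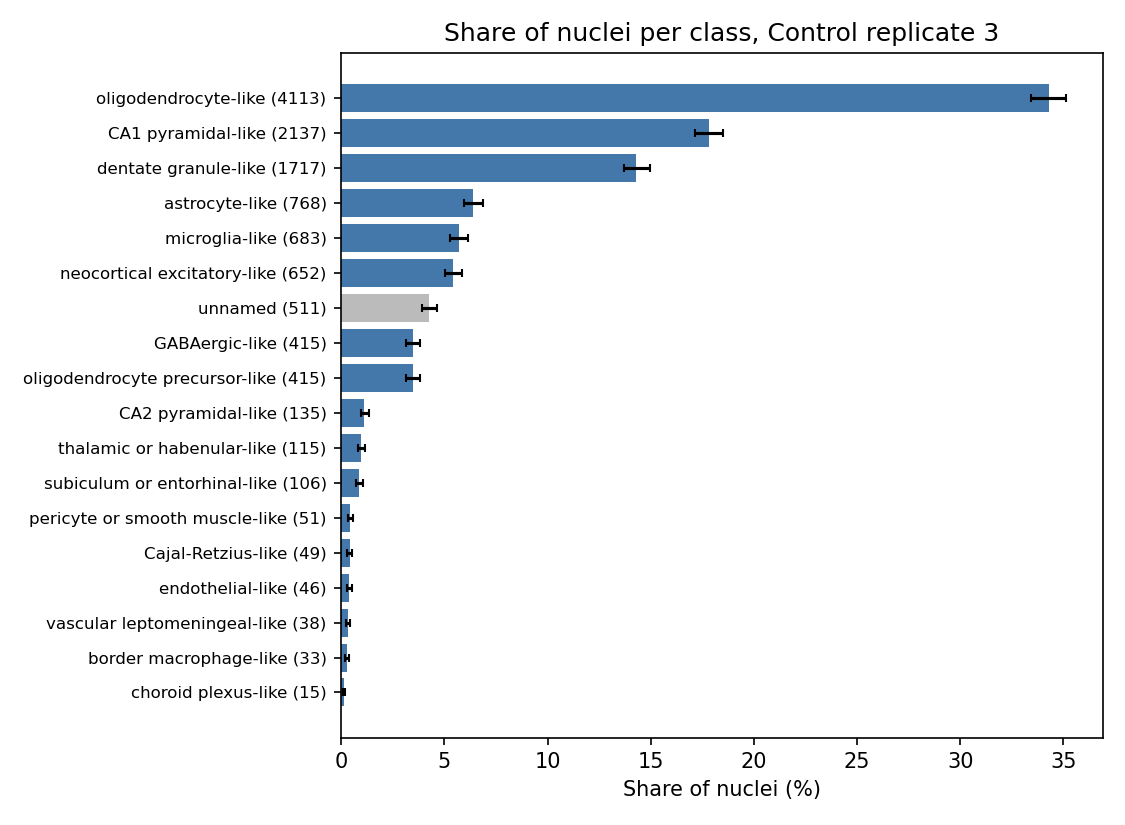
Bars show the share of the 11999 nuclei of Control replicate 3 in each class (percent of nuclei, horizontal axis), with the number of nuclei beside each name, and error bars show exact 95% binomial intervals. Oligodendrocyte-like nuclei were the largest class at 34.3%, followed by CA1 pyramidal-like at 17.8% and dentate granule-like at 14.3%.

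The neurogenic lineage was counted with fixed gene lists, to ask how many nuclei of the 1-year-old hippocampus carried transcripts of neuroblasts, stem cells or cycling cells. Nuclei with UMIs of 3 or more of 9 neuroblast genes numbered 32 of 11999, or 0.267% (0.182 to 0.376). If the genes were independent within each class, 57.9 such nuclei were expected, most of them in GABAergic-like nuclei, with 5 found against 28.8 expected, and neocortical excitatory-like nuclei, with 11 against 16.5. Dentate granule-like nuclei held 4 against 1.53 expected, a share of 0.233% (0.0635 to 0.595), and CA2 pyramidal-like nuclei 3 against 0.886. Oligodendrocyte-like nuclei, which should lack these genes, held 0 of 4113, which allows a share of up to 0.0729%, at a median depth of 1493 UMIs against 4651 in granule-like nuclei. Astrocyte-like nuclei held 0 of 768, which allows a share of up to 0.391%. After each nucleus was thinned to 1000 UMIs, 2 of 11142 nuclei remained. Of the single genes, Dcx, which encodes a microtubule-binding protein of migrating neuroblasts, reached 104.9 CPM (counts scaled to the total UMIs of a class) in GABAergic-like, 62.5 CPM in neocortical excitatory-like, 42.8 CPM in oligodendrocyte precursor-like and 6.42 CPM in dentate granule-like nuclei. Sox11, a transcription factor of immature neurons, stood at 49.4 CPM in dentate granule-like and 13.3 CPM in CA1 pyramidal-like nuclei. Igfbpl1, a marker of newborn neurons, had 42 UMIs in the whole set of nuclei. Eomes, which marks intermediate progenitors, had 3 UMIs, and Neurog2 had 6. Neurod1, a driver of granule neuron differentiation, was counted at 0 in every barcode. Its gene model lies inside that of Cerkl on the same strand, a position in which 416 of 417 protein-coding genes were counted at 0.

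Sox2, a transcription factor of neural stem cells and glia, reached 174 CPM in astrocyte-like, 109 CPM in oligodendrocyte precursor-like and 104 CPM in oligodendrocyte-like nuclei, against 34.1 CPM in GABAergic-like, 3.65 CPM in microglia-like and 1.22 CPM in dentate granule-like nuclei. Hopx, which marks quiescent stem cells and astrocytes of the dentate gyrus, stood at 302 CPM in astrocyte-like nuclei. Nes, which encodes the intermediate filament nestin, had 18 UMIs in the whole library. A single nucleus held 3 or more of 11 cell cycle genes, in the border macrophage-like class, against 0.657 expected in all classes and 0.0739 in its own if the genes were independent. The same nucleus held 4 or more, against 0.0160 expected in all classes. No dentate granule-like nucleus did, which allows a share of up to 0.175% of 1717, and no astrocyte-like nucleus did. Mki67, a protein of proliferating cells, had 130 of its 272 UMIs in dentate granule-like nuclei, at 14.4 CPM, and Top2a had 21 UMIs in all classes together.

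**Figure D2:**
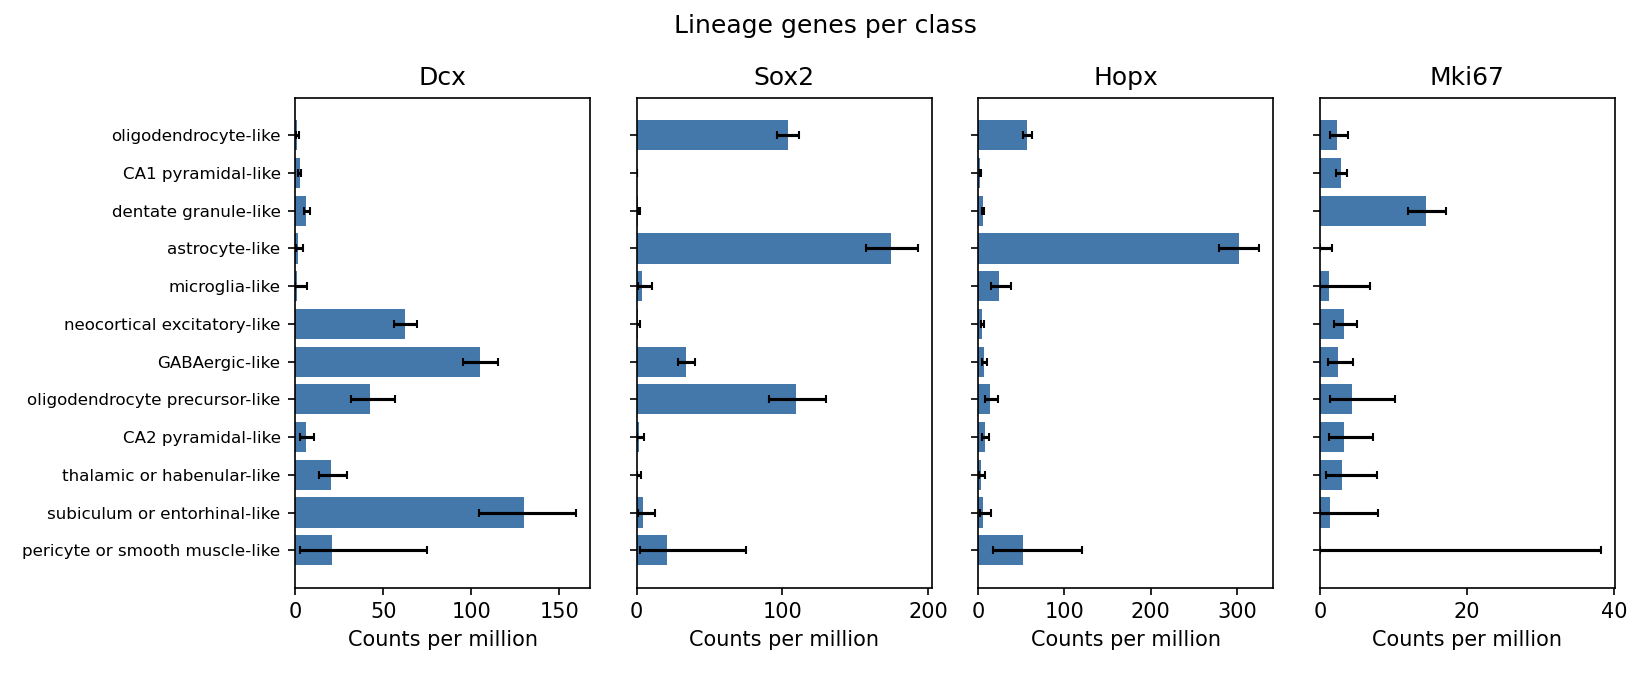
Each panel shows the level of a lineage gene (CPM, horizontal axis) in the classes of at least 50 nuclei of Control replicate 3, with exact 95% Poisson intervals as error bars. Dcx was highest in the subiculum or entorhinal-like class at 130 CPM and in GABAergic-like nuclei, Sox2 and Hopx in astrocyte-like nuclei, and Mki67 in dentate granule-like nuclei at 14.4 CPM.

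The comparison of astrocyte-like with dentate granule-like nuclei set 768 glial nuclei of the dissected tissue against the neurons born in the dentate gyrus. Gli2, a transcription factor of the hedgehog pathway (ENSMUSG00000048402, chromosome 1, 118834132 to 119053619, GRCm38), stood at 158 CPM against 0.111 CPM, a ratio of 1428 (255 to 56574) that rested on 1 granule-like UMI. Bmpr1b, a receptor for bone morphogenetic proteins, was 581-fold higher (294 to 1350) and Sox9, a glial fate factor, 396-fold higher (181 to 1084). Apoe, the main lipid carrier of the brain, stood at 8154 CPM against 39.6 CPM. Nrg3, a neuregulin ligand, ran the other way, at 24.1 CPM in astrocyte-like and 4054 CPM in granule-like nuclei.

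Of the 196 listed genes measured, 73 were at least 2-fold higher in astrocyte-like nuclei, 80 at least 2-fold lower and 43 neither. Of all 11612 genes measured, 19.0% were at least 2-fold higher and 20.8% at least 2-fold lower, without the rule on intervals. In the neural stem cell and quiescence list, 20 of 25 measured genes were higher, 1 (Frzb, a secreted Wnt inhibitor) lower and 4 neither. Thbs4 was 519-fold higher (176 to 2525), Nr2e1, a nuclear receptor that maintains stem cells, 277-fold (75.2 to 2311), Id4, an inhibitor of differentiation factors, 241-fold, Sox2 143-fold (79.2 to 289) and Gfap, the astrocytic filament protein, 73.2-fold (51.0 to 109). Of 21 Notch, Bmp, Wnt and hedgehog genes, 14 were higher, 0 lower and 7 neither, among them Gli3 with a ratio of 555, Notch1 with 43.3 (26.7 to 74.7) and Notch2 with 5.71 (4.82 to 6.77). The ageing, complement and reactive glia list had 12 of 14 higher and 2 lower, with Vcam1, an adhesion molecule, 382-fold higher (104 to 3175). Growth factors and receptors split into 7 higher, 9 lower and 5 neither, with Fgf1 238-fold higher (80.1 to 1166) and Ntrk3, the neurotrophin-3 receptor, 63.0-fold lower. Glutamate receptors were lower in 17 of 23 and higher in 5, with Grm7 117-fold and Grin2a 76.7-fold lower but Grin2c 345-fold higher. Voltage-gated channels were lower in 19 of 24 and higher in 1 (Kcna2), with Cacna1e, an R-type calcium channel, 106-fold lower and Kcnb2, a delayed rectifier, 71.7-fold lower. GABA-A receptors were lower in 8 of 11, with Gabrb2 64.3-fold lower, and higher in 2 (Gabrg1 and Gabrb1). Of the splicing regulators 7 were higher, 11 lower and 7 neither. Pou3f2, a neural transcription factor, was 230-fold higher (88.5 to 851), Rbfox3 fell among the lower genes at a ratio of 0.0287, and Ptbp1 (0.746, 0.367 to 1.39) and Ptbp2 (0.764, 0.654 to 0.889) were neither. Of 10 neuroblast genes, 5 were lower, 1 higher (Neurod6, 5.34) and 4 neither. Neurod6 stood at 403 CPM in CA1 pyramidal-like and 37.3 CPM in astrocyte-like nuclei. With background RNA subtracted its ratio was at least 79.0, a limit set because granule-like nuclei were left with fewer than 3 counts. At that limit most astrocyte-like UMIs of Neurod6 remained, so the share subtracted does not account for most of them. No other source was tested. In the same list, St8sia4 had a ratio of 0.0191 (0.00230 to 0.0694) and Dcx of 0.283 (0.0746 to 0.765). Of 4 cell cycle genes, Mki67 and Mcm6 (0.158) were lower. Mki67, with 0 UMIs in astrocyte-like nuclei, was 10.6-fold lower against 3 counts, and its exact interval allowed a ratio of up to 0.118. Immediate early genes gave 3 higher, 2 lower and 6 neither, and neuropeptides 1 higher (Sst, 3.08), 4 lower and 2 neither.

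Within the astrocyte-like class, a sub-cluster of 87 nuclei was led by the oligodendrocyte genes Mog and Mal and another of 78 nuclei by the neuronal genes Ralyl, Tenm2 and Grin2a. Without them, 70 listed genes were higher and 80 lower, and 6 of 32 named ratios moved by more than 1.5 times, among them Gabrb2 (0.00421), Nrg3 (0.00364), Grm7 (0.00525), Grin2a (0.00783) and Thbs4 (344). Subtracting background RNA, at the largest share that markers of other classes allowed, moved 18 of the 32 named ratios by more than 1.5 times. Of these, 16 became limits, with Apoe at least 22589, Grin2a at most 0.000641 and Nrg3 at most 0.000349. With predicted doublets kept 17 moved as far and Dcx (0.550) was no longer at least 2-fold lower.

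The comparison of dentate granule-like with CA1 pyramidal-like nuclei concerned the excitatory neurons that do and do not arise in the adult niche. Grm2, an inhibitory metabotropic glutamate receptor (ENSMUSG00000023192, chromosome 9, 106643095 to 106656082, GRCm38), stood at 24.8 CPM against 0.0984 CPM, a ratio of 252 (68.9 to 2093). Jag1, a Notch ligand, was 66.7-fold higher (22.1 to 330) and Notch2 33.7-fold (20.4 to 60.0). Kcnc2, a fast potassium channel, was 93.6-fold lower, at 4.10 CPM against 383 CPM.

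Of 189 listed genes measured, 47 were at least 2-fold higher in granule-like nuclei, 39 lower and 103 neither. The median of all 12938 genes measured was 0.15 higher on the log2 scale, and relative to it 40 listed genes were higher and 41 lower. Glutamate receptors were higher in 8 of 22 and lower in 0, with Grik3 35.2-fold, Grik4 13.6-fold and Grm8 12.4-fold higher. Immediate early genes were lower in 11 of 14, with Nr4a1 15.5-fold and Arc, a regulator of synaptic receptors, 13.7-fold lower, whereas Jun alone was higher, at 38.6-fold (27.7 to 55.3). Growth factors and receptors gave 9 higher, 3 lower and 12 neither, with Egfr 66.4-fold (17.6 to 561) and Ntf3, which encodes neurotrophin-3, 51.3-fold higher and Fgf1 at a ratio of 0.0277 (0.00567 to 0.0818). In the Notch, Bmp, Wnt and hedgehog list 6 were higher, 5 lower and 8 neither, with Smo, the hedgehog signal transducer, 13.9-fold higher and Dkk3 14.1-fold lower. Voltage-gated channels gave 6 higher, 5 lower and 14 neither, with Kcnd3 11.7-fold higher and Kcnq5, a channel of the M current, 27.0-fold lower. GABA-A receptors gave 2 higher (Gabrd and Gabra4), 2 lower (Gabrg3 and Gabra3, the latter 15.1-fold) and 7 neither. Of 24 splicing regulators, 2 were higher (Srrm4 and Celf4), 5 lower and 17 neither, with Khdrbs3 38.9-fold, Elavl4 17.0-fold and Pou3f2 12.9-fold lower. Ptbp1 had a ratio of 0.894 (0.662 to 1.20) and Ptbp2 1.51 (1.40 to 1.64). Neuroblast genes gave 4 higher, 2 lower and 5 neither, with Neurod6 57.8-fold lower and Dcx 2.51-fold higher (1.70 to 3.72). Of 6 cell cycle genes, Mki67 (5.04, 3.67 to 6.996), Mcm6 (10.9) and Tyms (2.57) were higher, 0 lower and 3 neither. The stem cell list gave 5 higher, among them Gfap at 2.49 (1.45 to 4.31), 2 lower and 7 neither. Neuropeptides gave 1 higher (Pdyn, 42.7-fold, 13.9 to 213), 3 lower and 4 neither, and the ageing list 0 higher, 1 lower (Lpl) and 10 neither. Sox2 and Notch1 had fewer than 50 UMIs over both classes.

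As an alternative, the CA2 pyramidal-like nuclei, whose cluster also scored on the CA3 list, were added to CA1. Ntf3 then fell to a ratio of 4.98, Notch2 to 4.56, Grik4 to 4.01, Jag1 to 21.8, Egfr to 36.2 and Grm8 to 6.90. Subtracting background RNA moved 15 of 31 named ratios by more than 1.5 times, 11 of them to limits, with Kcnq5 at most 0.000382 and Khdrbs3 at most 0.000413. It kept 41 of the 47 calls of higher genes. Gfap (1.86) and Dcx (1.97) were among those that ended, and Grm3 turned from higher to a ratio of 0.412. The share subtracted from granule-like nuclei was an upper limit, so these changes may come from removing too much.

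The comparison of GABAergic-like with excitatory-like nuclei (dentate granule-, CA1 and CA2 pyramidal-like, 3989 nuclei) concerned the inhibitory neurons, with 415 nuclei. Igf1, which encodes insulin-like growth factor 1 (ENSMUSG00000020053, chromosome 10, 87858265 to 87937042, GRCm38), stood at 142 CPM against 0.160 CPM, a ratio of 886 (378 to 2740). Grik1, a kainate receptor, was 375-fold higher (299 to 476). Dcx was 27.0-fold higher (22.0 to 33.3) and Sox2 59.0-fold (36.0 to 102). The excitatory-like group left out neocortical excitatory-like and subiculum or entorhinal-like nuclei. Dcx was far above the level of that group in the former and above the GABAergic-like level in the latter. Its ratio therefore holds only for the excitatory classes summed here. Neurod2 and Neurod6, transcription factors of excitatory neurons, were 21.9-fold and 13.3-fold lower, and Bdnf, brain-derived neurotrophic factor, 12.3-fold lower.

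Of 206 listed genes measured, 64 were at least 2-fold higher in GABAergic-like nuclei, 50 lower and 92 neither. The median of 13689 genes was 0.11 higher on the log2 scale, and relative to it 61 were higher and 54 lower. Of all 13689 genes, 12.9% were at least 2-fold higher and 9.88% at least 2-fold lower, without the rule on intervals. Neuropeptides were higher in 9 of 12, with Crh 359-fold (96.7 to 3009), Vip 264-fold, Sst 163-fold and Npy 111-fold, and Crhbp, a corticotropin-releasing hormone binding protein, 158-fold, while Cck (0.473) was lower. Glutamate receptors gave 9 higher, 4 lower and 10 neither, with Grm2 at a ratio of 0.101 (0.0208 to 0.300). Growth factors and receptors gave 9 higher, 4 lower and 14 neither, with Egfr 31.3-fold higher and Pdgfb 7.10-fold lower. Immediate early genes were lower in 8 of 15, with Arc 6.63-fold, Nr4a2 6.32-fold and Egr3 5.53-fold lower, and higher in 2 (Fosl2 and Dusp1). Neuroblast genes gave 6 higher, 3 lower and 3 neither, with Tac2, which encodes neurokinin B, 72.6-fold and Sema3c, a guidance cue, 29.4-fold higher. The Notch, Bmp, Wnt and hedgehog list gave 7 higher, 6 lower and 9 neither, with Dkk3 8.53-fold and Notch2 3.72-fold lower and Jag1 at a ratio of 0.154 (0.0184 to 0.572). Voltage-gated channels gave 5 higher, 6 lower and 14 neither, with Cacna1e 7.33-fold lower, and GABA-A receptors 4 higher, 4 lower and 4 neither. Splicing regulators gave 5 higher, 5 lower and 15 neither, with Ptbp1 at 1.20 (0.832 to 1.70) and Ptbp2 at 1.02 (0.916 to 1.14), or 0.945 relative to the median gene. The stem cell list gave 3 higher, 4 lower and 9 neither, with Gfap at 1.04 (0.427 to 2.18), or 0.958 relative to the median gene. The ageing list gave 4 higher, 3 lower and 4 neither, with Serpina3n, a protease inhibitor, 8.31-fold lower. The cell cycle list gave 1 higher (Ccnb2, 3.06), 2 lower (Mcm6, 0.211, and Mki67, 2.54-fold lower) and 3 neither.

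Of the 3 GABAergic-like clusters, cluster 13 (222 nuclei, led by Sst) had no GABAergic marker and 1 marker of the Cajal-Retzius list (Cacna2d2) among its 10 leading genes, although 11 of 12 markers were raised in it. Without it 13 of 31 named ratios moved by more than 1.5 times, among them Sst (15.4), Crhbp (9.27), Vip (563), Tac2 (162), Egfr (67.5), Sema3c (62.7), Igf1 (1608), Arc (0.0671) and Egr3 (0.0447), Mki67 (0.701) was no longer at least 2-fold lower and Ptbp1 stood at 0.847. Subtracting background RNA moved 13 of 31 named ratios by more than 1.5 times, 4 of them to limits, with Grik1 at 7509.

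The comparison of microglia-like with astrocyte-like nuclei set 683 nuclei like those of resident immune cells against a glial class of another origin. Tgfb1, transforming growth factor beta 1 (ENSMUSG00000002603, chromosome 7, 25687002 to 25705077, GRCm38), stood at 180.3 CPM against 0.454 CPM, a ratio of 397 (70.1 to 15779) that rested on 1 astrocyte-like UMI, and its receptors Tgfbr1 and Tgfbr2 were 86.6-fold and 69.0-fold higher. The complement genes C1qa, C1qc and C1qb were 197-fold, 156-fold and 116-fold higher. Trem2, a lipid-sensing receptor, and its adaptor Tyrobp were 206-fold (69.5 to 1004) and 62.4-fold higher. Clu, a secreted chaperone, was 64.0-fold lower, at 51.2 CPM against 3274 CPM.

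Of 143 listed genes measured, 28 were at least 2-fold higher in microglia-like nuclei, 76 lower and 39 neither. The median of 8174 genes was 0.41 higher on the log2 scale, and relative to it 20 were higher and 83 lower. Of all 8174 genes, 29.1% were at least 2-fold higher and 18.4% at least 2-fold lower, without the rule on intervals. The listed genes split the other way, so their split describes the lists, not all genes. The ageing, complement and reactive glia list gave 10 higher, 6 lower and 3 neither, with Cd68, a lysosomal protein, 217-fold higher (37.9 to 8683). Growth factors and receptors gave 5 higher, 11 lower and 3 neither, with Pdgfb 201-fold higher (35.0 to 8048) and ratios of 0.00478 (0.000121 to 0.0267) for Egfr, 0.00711 (0.000180 to 0.0399) for Vegfa and 0.0154 (0.00317 to 0.0453) for Fgfr1. Cd68, Pdgfb, Egfr, Vegfa and Gabrg1 each rested on 1 UMI in the lower class. The stem cell list was lower in 19 of 23 and higher in 0, with Nfib 118-fold and Gfap 34.4-fold lower and ratios of 0.0114 (0.00138 to 0.0415) for Id4 and 0.0209 (0.00430 to 0.0617) for Sox2. The Notch, Bmp, Wnt and hedgehog list gave 13 lower, 2 higher (Rbpj and Smad1) and 4 neither. Bmpr1b had a ratio of 0.00473 (0.000573 to 0.0171). Gli3, with 0 UMIs in microglia-like nuclei, was 101-fold lower against 3 counts, and its exact interval allowed a ratio of up to 0.0122. Notch1 was 2.44-fold lower, and Notch2 had a ratio of 1.08 (0.874 to 1.32), or 0.808 relative to the median gene. Glutamate receptors were lower in 12 of 14, with Grm3 94.4-fold lower and Grin2c at a ratio of 0.0192 (0.00393 to 0.0564), and GABA-A receptors in 5 of 7, with Gabrb1 133-fold lower and Gabrg1 at a ratio of 0.00979 (0.000247 to 0.0550). Splicing regulators gave 4 higher, 4 lower and 10 neither, with Mbnl1, a muscleblind splicing factor, 13.03-fold and Ptbp3 10.9-fold higher (8.50 to 14.0), and Ptbp2 at 1.77 (1.41 to 2.22). Voltage-gated channels gave 3 higher, 5 lower and 3 neither. Neuroblast genes gave 1 higher (Sox4, 4.78), 1 lower (Ncam1) and 3 neither, immediate early genes 1 higher (Junb, 5.95) and 4 neither, and neuropeptides 2 higher (Sst, 2.59, and Cck, 2.10) and 1 neither. Sst and Cck are neuronal genes, and with estimated background RNA subtracted, 11.2% in microglia-like and 5.09% in astrocyte-like nuclei, their ratios were 2.84 and 2.23. No cell cycle gene reached 50 UMIs over both classes, nor did Dcx or Ptbp1.

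The median depth was 1099 UMIs in microglia-like and 2654.5 in astrocyte-like nuclei. With 1000 or more genes required 66 listed genes were higher and 49 lower, so that 57.4% of calls were higher in place of 26.9%. Of 32 named ratios, 28 then moved by more than 1.5 times, with Nfib at 0.297 and Gabrb1 at 0.150. With predicted doublets kept the split was 35 higher and 58 lower, or 37.6%. In that setting 18 named ratios moved as far, with Nfib at 0.188 and Gabrb1 at 0.104. Ratios of CPM are scaled to the UMIs of a class, so depth alone does not set them. Why the ratios moved was not tested.

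**Figure D3:**
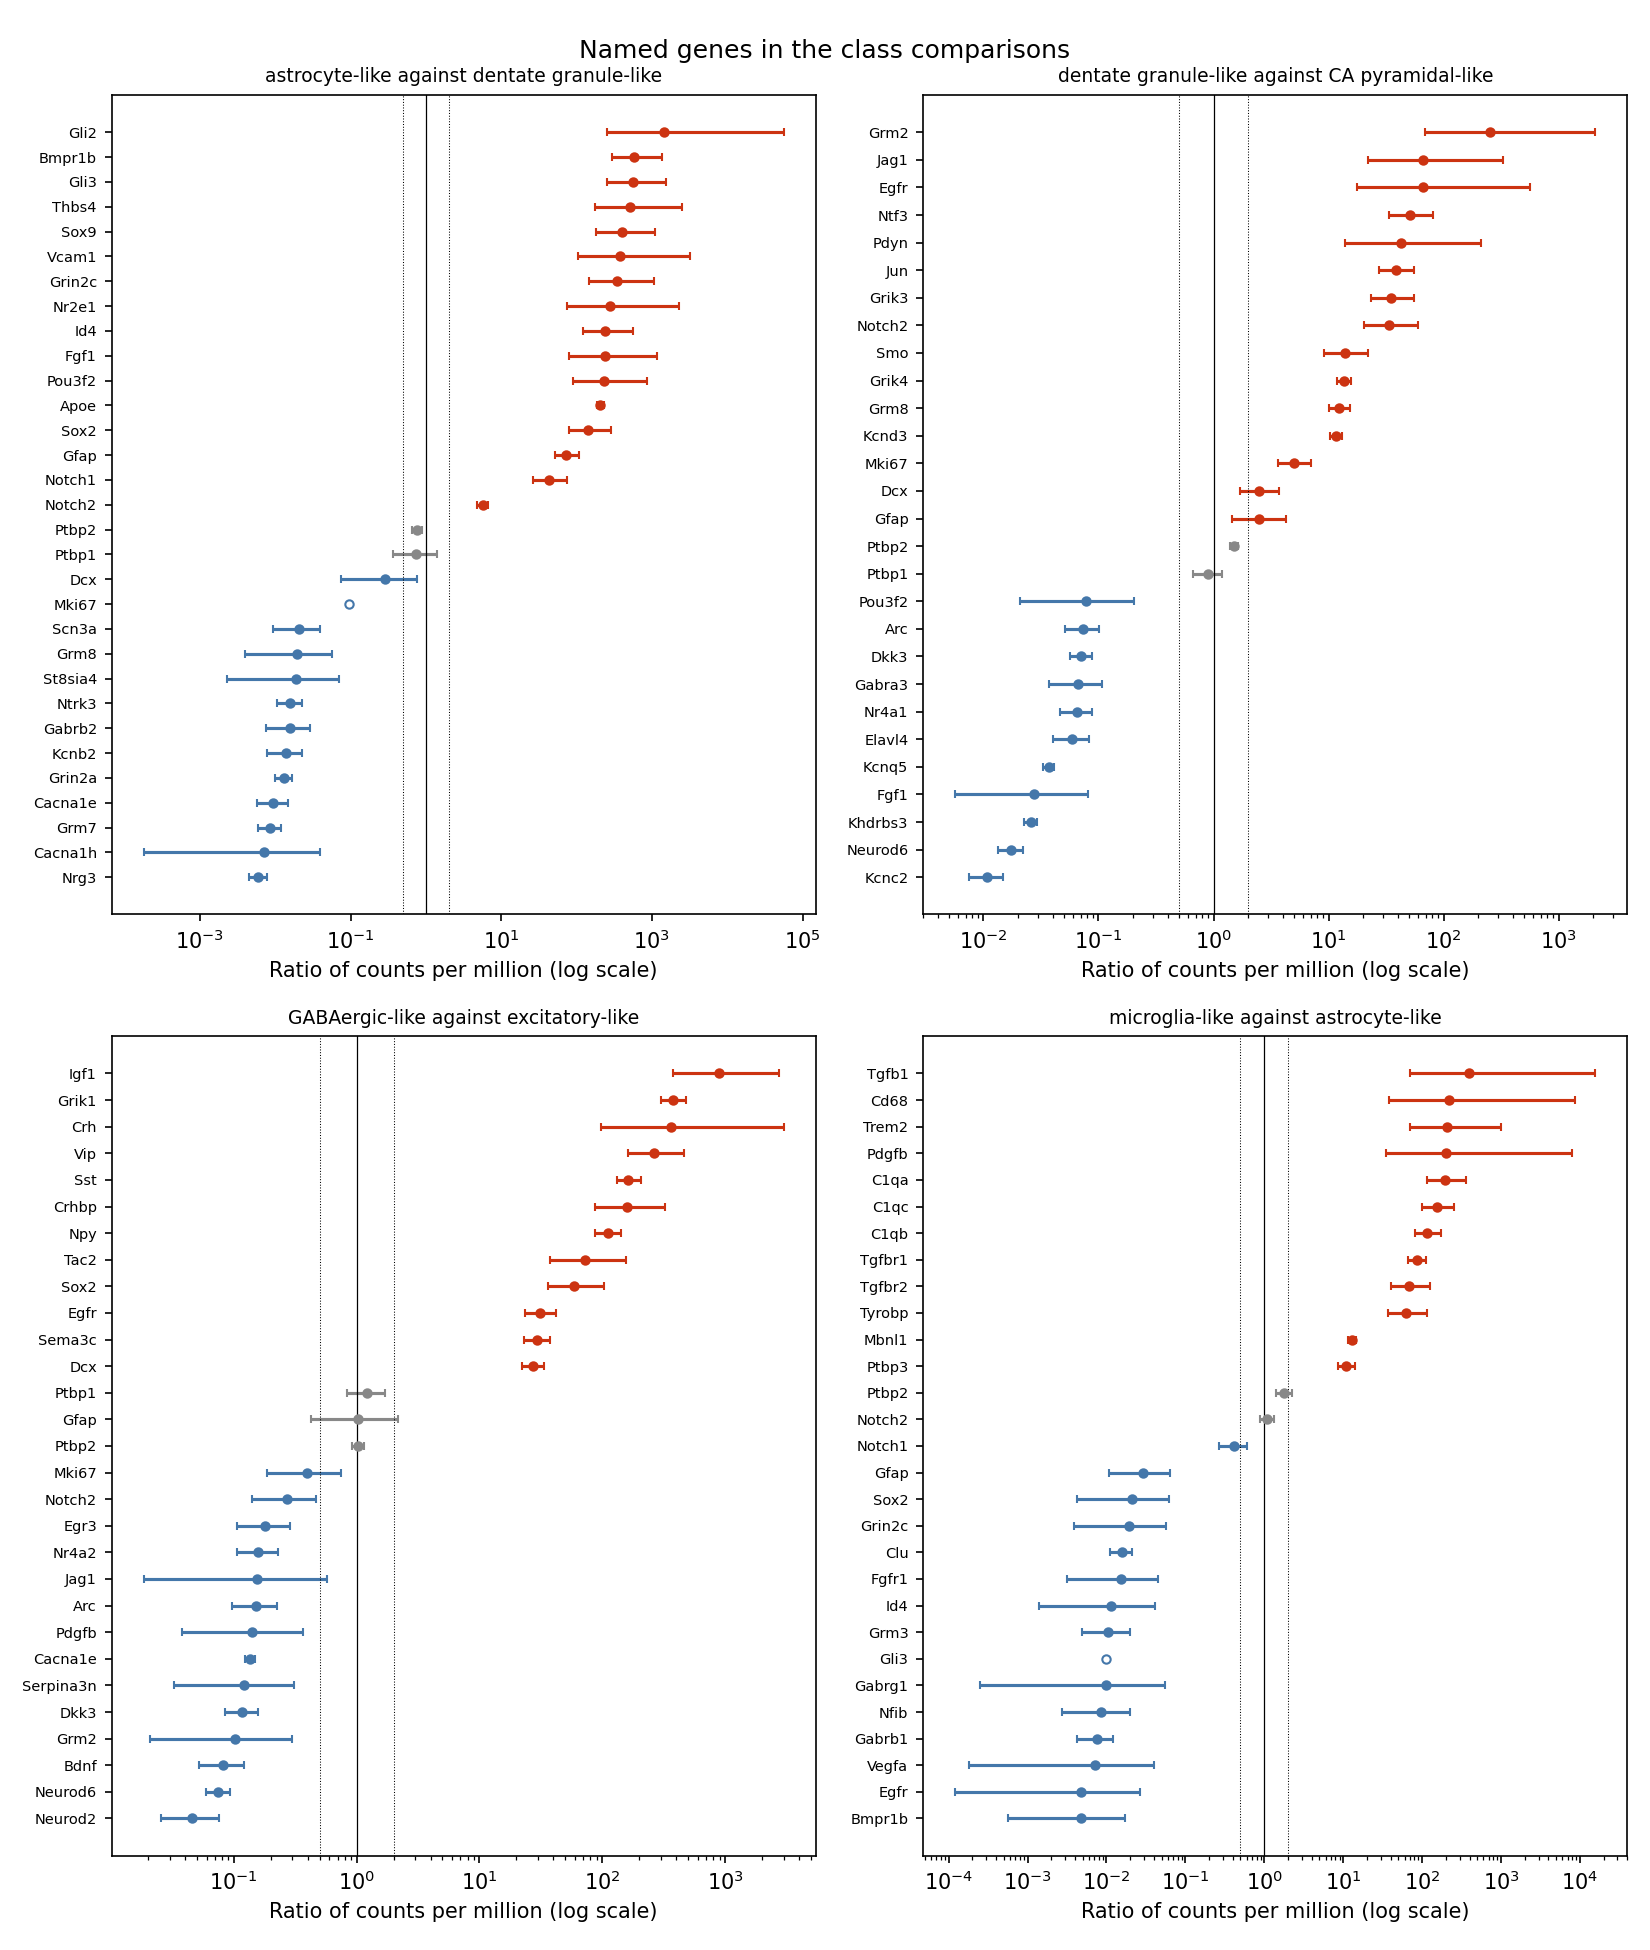
Points show the ratio of CPM (log scale, horizontal axis) of named genes in the 4 comparisons of classes in Control replicate 3, with exact 95% conditional intervals as bars, and open circles mark limits where a class had 0 UMIs. Red and blue points are genes called higher and lower, grey points neither, and dotted lines mark 2-fold. Gli2 reached a ratio of 1428 in astrocyte-like against dentate granule-like nuclei, and Igf1 886 in GABAergic-like against excitatory-like nuclei.

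The polypyrimidine tract binding (PTB) family was compared across classes because Ptbp1 represses neuronal splicing in non-neuronal cells and gives way to Ptbp2 as neurons form. Ptbp1 (ENSMUSG00000006498, chromosome 10, 79854427 to 79864771, GRCm38) stood at 31.1 CPM or less in each class of at least 50 nuclei, with the highest value from 3 UMIs in pericyte or smooth muscle-like nuclei. It reached 5.45 CPM (2.82 to 9.52) in astrocyte-like, 4.69 CPM (3.20 to 6.61) in oligodendrocyte-like, 7.31 CPM (5.65 to 9.29) in dentate granule-like and 8.17 CPM (6.97 to 9.51) in CA1 pyramidal-like nuclei. Microglia-like nuclei had 20.7 CPM (12.1 to 33.2), from 17 UMIs, a ratio of 3.80 (1.71 to 8.72) to astrocyte-like nuclei, with fewer than 50 UMIs over both classes, and of 2.83 (1.56 to 4.89) to granule-like nuclei. With 1000 or more genes required the former Ptbp1 ratio was 2.50. The astrocyte-like level did not differ from the granule-like level beyond counting error, with a ratio of 0.746 (0.367 to 1.39).

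Ptbp2 (ENSMUSG00000028134, chromosome 3, 119718742 to 119784466) had more UMIs than Ptbp1 in glia as well as in neurons. Its gene is the longer of the pair, counts were not adjusted for length, and whether intronic reads were counted is not known. The UMIs therefore do not rank the abundance of the transcripts. The Ptbp2 level was 125 CPM in oligodendrocyte-like, 152 CPM in oligodendrocyte precursor-like, 162 CPM in microglia-like, 119.5 CPM in dentate granule-like, 92.9 CPM in GABAergic-like, 91.3 CPM in astrocyte-like and 78.9 CPM in CA1 pyramidal-like nuclei. There were 26.7 Ptbp2 UMIs per Ptbp1 UMI (18.8 to 39.3) in oligodendrocyte-like, 16.8 (9.38 to 33.0) in astrocyte-like, 16.4 (12.8 to 21.3) in granule-like and 9.66 (8.23 to 11.4) in CA1 pyramidal-like nuclei. Ptbp3 (ENSMUSG00000028382, chromosome 4, 59471868 to 59549364), the family member of blood cells, ranged from 404 CPM (362 to 450) in microglia-like nuclei to 19.7 CPM in thalamic or habenular-like nuclei, with 37.3 CPM in astrocyte-like and 113 CPM in CA1 pyramidal-like nuclei. The share of nuclei with a Ptbp3 UMI was 36.2% in microglia-like and 59.4% in the deeper CA1 pyramidal-like nuclei. After thinning to 1000 UMIs these shares were 32.0% and 10.4%, and the shares with a Ptbp1 UMI were 1.69% and 0.608%. Thinning left out 268 microglia-like and 550 oligodendrocyte-like nuclei and none of the CA1 pyramidal-like.

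Among the neuronal splicing regulators, Rest, a repressor of neuronal genes, stood at 20.4 CPM (14.9 to 27.4) in astrocyte-like and 19.2 CPM in oligodendrocyte precursor-like nuclei, against 1.23 CPM (0.796 to 1.82) in CA1 pyramidal-like nuclei. Srrm4, which drives neuronal microexon splicing, stood at 188 CPM in GABAergic-like and 90.7 CPM in granule-like nuclei and at 4.25 CPM in oligodendrocyte-like nuclei. Rbfox3, which encodes the neuronal antigen NeuN, stood at 396 CPM in granule-like and 315 CPM in CA1 pyramidal-like nuclei against 11.4 CPM in astrocyte-like nuclei. Nova1 reached 499 CPM in oligodendrocyte precursor-like nuclei, Qk, a glial RNA-binding protein, 3591 CPM in oligodendrocyte-like nuclei, and Msi1, a stem cell RNA-binding protein, 70.9 CPM in astrocyte-like nuclei.

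**Figure D4:**
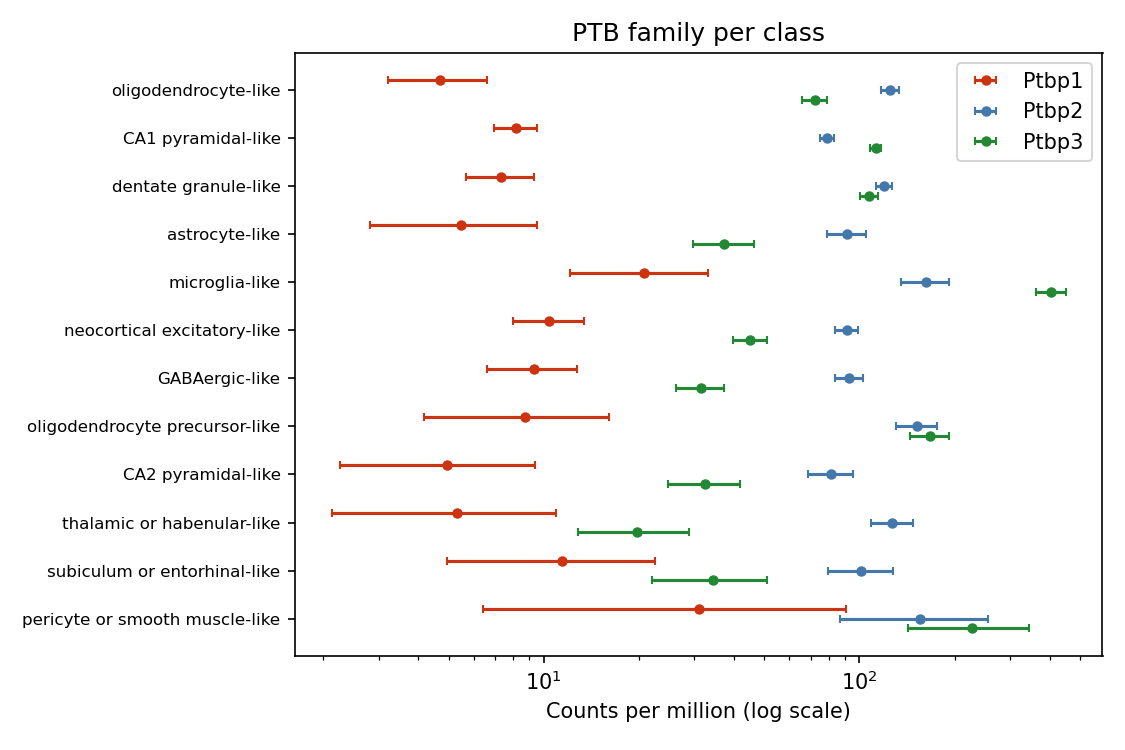
Points show the level of Ptbp1, Ptbp2 and Ptbp3 (CPM, log scale, horizontal axis) in the classes of at least 50 nuclei of Control replicate 3, with exact 95% Poisson intervals as bars. Ptbp1 lay below Ptbp2 in each plotted class, and Ptbp3 was highest in microglia-like nuclei at 404 CPM.

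The barcode lists allowed the 3 libraries to be compared in size only. Replicate 1 held 18307 barcodes, replicate 2 held 27005 and replicate 3 held 13426, against 12000 nuclei loaded per the labels, or 1.53, 2.25 and 1.12 barcodes per nucleus loaded. Whether more nuclei were loaded or some barcodes stand for no nucleus was not tested. Replicates 1 and 2 shared 151 barcode sequences, replicates 1 and 3 shared 66, and replicates 2 and 3 shared 99. If barcodes were drawn at random, these numbers correspond to lists of 3274043 (2791583 to 3866086), 3724088 (2927178 to 4815216) and 3662314 (3008150 to 4506074) sequences. The length of the barcode list of the kit on the labels is not given in the sources used here, so the kit and the transcript end it reads were left open.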

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

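Of the alternative values of the main class shares, candidate shares and gene counts, 197 stayed within the reported 95% interval, or within 1.5 times a reported count, and 26 did not. With 200 or more genes required, the oligodendrocyte-like share was 37.4%, CA1 pyramidal-like 16.5%, dentate granule-like 13.3% and microglia-like 6.52%, and with 1000 or more genes 15.3%, 25.8%, 20.7% and 2.45%. The last setting removes shallow nuclei and so lowers the shares of shallow classes by construction. With the 12000 deepest barcodes the shares were 33.3%, 18.5%, 15.1% and 4.30%, and with doublets kept 33.1% oligodendrocyte-like and 17.1% CA1 pyramidal-like. With 2 genes required, neuroblast candidates were 3.03% and cycling candidates 0.158%, with 4 genes neuroblast candidates were 0.0167%, with 2 or more Igfbpl1 UMIs, chosen after seeing the data, 0.0833%, and with 1000 or more genes cycling candidates were 0. A ratio threshold of 4 gave 24 higher and 22 lower genes in granule-like against CA1 pyramidal-like, 36 and 20 in GABAergic-like against excitatory-like and 16 and 62 in microglia-like against astrocyte-like nuclei, fewer by construction. With 1000 or more genes the last comparison gave 66 higher and 49 lower. The cause of the other differences was not tested. Of the alternative ratios of named genes, 1624 stayed within the reported interval, 140 did not, 28 of them limits with background RNA subtracted, and 0 turned the direction of a call. Outside the named genes, Grm3 turned from higher to lower in granule-like against CA1 pyramidal-like nuclei with background RNA subtracted. Of 126 named ratios, 49 moved by more than 1.5 times with background RNA subtracted, 34 of them to limits, 39 each with doublets kept and with 1000 or more genes and 20 with a mean over nuclei. The background shares were upper limits, so that setting can remove too much. Calls of named genes ended for Gfap (1.86) and Dcx (1.97) in granule-like against CA1 pyramidal-like nuclei with background subtracted, for Mki67 (0.701) in GABAergic-like nuclei without cluster 13, chosen after seeing the data, and for Dcx (0.550) in astrocyte-like against granule-like nuclei with doublets kept. No paired analysis was possible because only 1 library had a matrix used here, and no library could be left out for the same reason. CA3 pyramidal-like nuclei alone could not be compared because no such cluster was named, and CA1 alone is the comparison reported. Depth limits genes with fewer than 50 UMIs over both classes, among them Mki67, Dcx and Ptbp1 in microglia-like against astrocyte-like nuclei.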

Other observations

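Of the tests below, the test of genes counted at 0 was chosen before its shares were seen, and the other 5 tests and both comparisons of clusters within a class were chosen after the result was seen. Genes named here were likewise chosen after their values were seen, and intervals are exact 95% intervals that cover counting error only. The 4113 oligodendrocyte-like nuclei fell into 2 groups of clusters. Clusters 6 and 9, with 1189 nuclei or 9.91%, had Enpp6, a phosphodiesterase, and Anln among their leading genes, beside Carns1 and Serpinb1a. The list of committed oligodendrocyte precursors scored second in them, with mean log2 folds of 0.22 and 0.426. The oligodendrocyte list scored 3.071 and 3.332, so newly formed cells were not shown. Clusters 3 and 4, with 2924 nuclei or 24.4%, were led by Opalin, a myelin protein. Of the 128 listed genes measured, 1 was at least 2-fold higher in clusters 6 and 9, 6 were lower and 121 neither. Grm8, a presynaptic glutamate receptor, was 4.17-fold higher (2.77 to 6.40). St8sia4, a polysialyltransferase, had a ratio of 0.248 (0.147 to 0.395), Gabra2 of 0.400 (0.202 to 0.732), Cd9, a tetraspanin, of 0.462 (0.420 to 0.507) and Kcna2 of 0.475 (0.342 to 0.648).

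Within the astrocyte-like class, sub-cluster 9 held 36 nuclei and was led by Myoc, Serpinf1 and Aebp1. Of 23 genes of the stem cell list measured in it, 8 were at least 2-fold higher than in the other astrocyte-like nuclei, 0 lower and 15 neither. Fabp7, a fatty acid binding protein of radial glia, was 11.1-fold higher (6.74 to 18.1), Id1 9.63-fold (5.87 to 15.6), Id3 4.78-fold (3.94 to 5.77), Gfap 4.00-fold (3.21 to 4.94), Vim 3.30-fold (2.36 to 4.51) and Hopx 2.58-fold (2.04 to 3.22). Sox2 had a ratio of 0.941 (0.576 to 1.46), Thbs4 of 0.717 (0.406 to 1.18) and Notch2, which is outside that list, of 0.659 (0.347 to 1.14). Of the marker lists, that of ependymal cells came closest to this sub-cluster, which stayed unnamed because none of those markers was among its 25 leading genes.

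The labels put all libraries in a single group, so no biological explanation given by the design was tested. Mki67 had 130 UMIs in 117 of the 1717 dentate granule-like nuclei, with at most 3 in a nucleus and 2 or more in 11 nuclei, against 5.81 expected by depth. The 117 nuclei held 1 UMI of the 10 other cell cycle genes and the 1600 others 37, a rate ratio of 0.281 (0.00692 to 1.66), which argues against cycling nuclei as the source. The level was 6.14 times that in oligodendrocyte-like nuclei (3.64 to 11.1), which argues against free RNA spread alike over droplets. Low transcription of the gene in granule neurons, or transcripts of the opposite strand counted as Mki67, stay open and were not tested.

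Igfbpl1 had 2 or more UMIs in 10 nuclei, or 0.0833% (0.0400 to 0.153), of which 5 were dentate granule-like, 3 CA2 pyramidal-like, 1 CA1 pyramidal-like and 1 GABAergic-like. If its 42 UMIs had fallen on nuclei by depth, 0.139 such nuclei were expected, which argues against free RNA. Their median depth was 0.265 of the median of their own cluster, with 9 of 10 below it, which argues against doublets as a set, while the CA1 pyramidal-like nucleus of 14553 UMIs lay above it. The other neuroblast genes had 30 UMIs in 9 of the 10 nuclei, against 49 UMIs in 31 of 105 nuclei of the same classes and nearest depth, a rate ratio of 11.3 (6.94 to 18.2). As a hypothesis, these nuclei may be rare immature neurons assigned to mature classes, and a technical source that raises several neuroblast genes together stays open.

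Of 417 protein-coding genes that lie wholly inside another listed gene on the same strand, 416 were counted at 0 (99.8%, 98.7 to 100.0). Of 756 inside a gene on the opposite strand, 125 were at 0 (16.5%, 14.0 to 19.4), a ratio of 6.03, and of the 20801 other genes 3059 (14.7%, 14.2 to 15.2). These shares are consistent with reads that match gene models on the same strand being left out of the counts, so that a 0 of Neurod1 (inside Cerkl), Tubb3 (inside Gm20388) or Cntf (inside Zfp91) may say nothing of expression. Igf2, also at 0, lies inside no other gene, so its 0 stays open.

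Cdkn2a, a cell cycle inhibitor used as a marker of senescent cells, had 18 UMIs in oligodendrocyte precursor-like nuclei, at 15.7 CPM (9.32 to 24.9). Its level was 0.586 CPM (0.160 to 1.499) in oligodendrocyte-like nuclei. Whether any nucleus was senescent was not tested, and levels in the other classes are not given here.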
